A study of Mus musculus with 24 samples.

How the data were processed

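The series holds 24 Affymetrix mouse expression arrays of total RNA from mouse brain, 1 colour each, from a selection experiment in mice descended from the inbred strains A/J and C57BL/6J. The title of the series names contextual fear conditioning, in which a mouse learns to freeze in a place where it received a shock. The labels put each array in 1 of 4 groups of 6 arrays: hippocampus or amygdala, from animals described as low or high freezing. Nothing in the labels says whether an array holds RNA of 1 animal or of several, so p-values measure the spread between these arrays.

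The deposited values are linear intensity values, 1 per probe set, for 45101 probe sets on each array; the software that made them is not given in the sources used here. Judged from the deposited intensity values, each array's mean without its top and bottom 2% was 150, as a scaling of every array to 1 target would give. Array medians lay between 36.9 and 43.6 intensity units. Arrays have no read depth, and their number, 6 per group, limits the precision.

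Values were tested as log2(intensity + 16), so folds are on that scale and understate the change of dim probe sets. On that scale the array medians spanned 0.173, under the limit of 0.2 set for taking a table as already normalized, and no further normalization was applied; without the offset of 16 the span was 0.242, so quantile normalization is among the alternatives. The 64 control probe sets were left out, and so was the dimmest 40% of probe sets by mean over all arrays, which left 27022. The lowest mean kept was 23.35 intensity units.

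Gene symbols came from the platform annotation given for these probe sets: 34958 carried 1 symbol, 932 carried several and 9211 carried none here. Probe sets without exactly 1 symbol are counted but not named. Chromosomes and the order of genes along them came from a RefSeq gene table of assembly GRCm38.p6; the deposited table names no build, so no coordinates are given. Tests per gene used the brightest of a gene's probe sets, 12471 genes in all.

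A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior and 20 residual degrees of freedom. It gave 4 comparisons: high minus low freezing in the hippocampus, the same in the amygdala, amygdala minus hippocampus averaged over both freezing groups, and the difference between the regional freezing differences (interaction). All limma tests were two-sided with Benjamini-Hochberg adjustment over the probe sets kept, at a threshold of 0.05. The mean of the freezing differences of both regions was added as a further comparison after the values had been seen.

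Before the data were examined, 22 lists of genes by function and 16 lists of cell type or region markers were fixed, with 431 of their 535 genes measured. Lists with at least 3 measured genes, 37 of them, were tested with camera, which asks whether a list's genes are higher or lower than the other genes. The preset correlation between genes was 0.01, and adjustment ran over all 148 tests. Camera with a correlation estimated from these arrays was the alternative. The list of blood cell markers had 1 measured gene and was not tested.

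The genes named were chosen by a rule fixed at the same time: per comparison the 10 highest and 10 lowest log2 differences past the threshold, up to 4 members of each list past the threshold, and 6 genes with known variants between or within the parental strains. For the interaction it was the 5 smallest p-values where none passed, and the same for comparisons with fewer than 5 genes. For the region comparison only part of the genes that the rule selects are named in the results. Left out there are, among others, Ecrg4 (17.2-fold) and Shox2 (10.3-fold), both higher in the amygdala, and Ccn3 (7.18-fold lower). Other probe sets named were chosen after their values were seen; these are the called probe sets that are not their gene's brightest, list members that did not pass, and the genes of the averaged comparison.

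The model was tested on simulated arrays with the real means and spreads of the 27022 probe sets. For the hippocampal freezing comparison it recovered 56 of 100 probe sets changed by 0.5 on the log2 scale and 97 of 100 changed by 1, with 8 calls among the unchanged ones. The simulated probe sets were drawn independently of each other, so false calls among the real, correlated ones cannot be judged from this. The planted changes also outnumbered the real calls of the freezing comparisons in 1 region, which eases the adjusted threshold. The recovery may therefore be too high for those comparisons.

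Alternatives changed 1 choice at a time: an offset of 1 or 64, quantile normalization, centring arrays on their median, no filter on dim probe sets, leaving out the dimmest 60%, a variance prior without trend, a robust prior, array weights, each region fitted alone, the replicate number as a block, 1 probe set per gene, the mean of a gene's probe sets, and each array left out in turn. Single values, such as control ratios, were compared with exact two-sided permutation tests.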

Results

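Expression was measured in the hippocampus and the amygdala of mice from a cross between the inbred strains C57BL/6J and A/J, with 6 arrays for each region from animals labelled low freezing and 6 from animals labelled high freezing. Both regions take part in learned fear: the hippocampus in memory of the place, the amygdala in the association with the aversive event. Arrays of 1 group correlated with each other between 0.979 and 0.995 across probe sets, and no pair within a group held identical values. Median intensity was higher in the high freezing arrays of the hippocampus, 39.96 ± 1.65 against 37.84 ± 0.744 (SD, n = 6 each; exact permutation p = 0.026, adjusted p = 0.0843 over 6 tests). In the amygdala it was 42.67 ± 0.789 against 40.98 ± 1.38 (exact permutation p = 0.0281, adjusted p = 0.0843, n = 6 each). The ratios of 3' to 5' control probe sets for Gapdh and actin, a measure of RNA integrity, did not pass this test in either region, with exact p between 0.0866 and 0.656.

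Amygdala and hippocampus differed far more from each other than the freezing groups did. Penk, which encodes the enkephalin precursor, stood at 3474 ± 914 intensity units in the amygdala and 179 ± 33.4 in the hippocampus (SD, n = 12 each), 17.5-fold higher. Isl1, a transcription factor of striatal projection neurons, was 15.2-fold higher, and Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, 9.37-fold. In the other direction Lct was 12.3-fold higher in the hippocampus, 291 ± 51.8 against 9.55 ± 7.42 units, and the neuronal transcription factor Neurod6 9.18-fold. Of 27022 probe sets, 13832 (51.19%) passed the threshold, 7310 higher in the amygdala and 6522 lower, and 1501 of them differed at least 2-fold. The balance turned with the scaling: 6670 were higher and 7328 lower with quantile normalization, and 6354 higher and 7673 lower with arrays centred on their median.

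Lists of hippocampal markers separated the regions, but the identity of the amygdala samples was less clear. The list of basolateral amygdala and claustrum markers did not pass, and its means were lower in the amygdala arrays. Its mean log2 intensity per array was 7.86 ± 0.287 in the high and 7.69 ± 0.268 in the low freezing amygdala (SD, n = 6 each). In the hippocampus it was 8.40 ± 0.088 and 8.38 ± 0.0814. Among its members with the largest differences, Neurod6, Nr4a2 (6.01-fold) and Rspo2 (3.74-fold) were lower in the amygdala, and Otof was 2.91-fold higher. All 9 measured markers of dentate gyrus granule cells were lower in the amygdala, with a median log2 difference of -1.70 (camera adjusted p = 7.42e-09), among them Dsp (6.87-fold lower), C1ql2 (6.86-fold) and Tdo2 (5.18-fold). Of 11 markers of the CA fields, 10 were lower and 1 higher (adjusted p = 1.31e-06); Fibcd1 was 6.32-fold lower and Spink8 4.10-fold. Excitatory neuron markers were lower in 7 of 8 cases (adjusted p = 2.79e-05), including Slc17a7, the vesicular glutamate transporter of cortical neurons, at 4.77-fold. The dentate and CA calls held with an estimated correlation (adjusted p = 0.00537 for each), and the excitatory call did not (adjusted p = 0.13 with an estimated correlation).

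Higher in the amygdala were 14 of 15 markers of the central amygdala and striatum (adjusted p = 3.51e-10), among them the dopamine receptors Drd1 (8.11-fold) and Drd2 (6.75-fold). As elsewhere for the regions, this counts members past the threshold, and all 15 were above 0. All 13 measured oligodendrocyte markers were higher (adjusted p = 3.52e-12), with a median log2 difference of 2.09; Ermn, Mog and Mal, genes of myelin, were 5.47-, 5.15- and 5.09-fold higher. All 10 markers of choroid plexus and ependyma were higher too (adjusted p = 6.58e-06), among them Clic6 (12.7-fold), Folr1 (9.02-fold) and Kcne2 (8.29-fold), as was Kcnj13 (9.84-fold), named outside that list. Markers of thalamus, hypothalamus and midbrain were higher in 12 of 15 cases and lower in 1 (adjusted p = 0.000969), with 14 above 0. They included the hypothalamic peptide genes Avp at 6.32-fold and Pmch at 5.66-fold. Both varied widely between the amygdala arrays, at 233.3 ± 240 and 283.9 ± 171 units (SD, n = 12). The choroid plexus list and the list of thalamus, hypothalamus and midbrain name tissue outside the amygdala. The share of such tissue was not measured, so the regional differences, also those of single genes below, are between dissected samples. With an estimated correlation the adjusted p was 0.13 for the central amygdala list, 0.13 for oligodendrocytes and 0.446 for each of the other 2 lists.

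**Figure D1:**
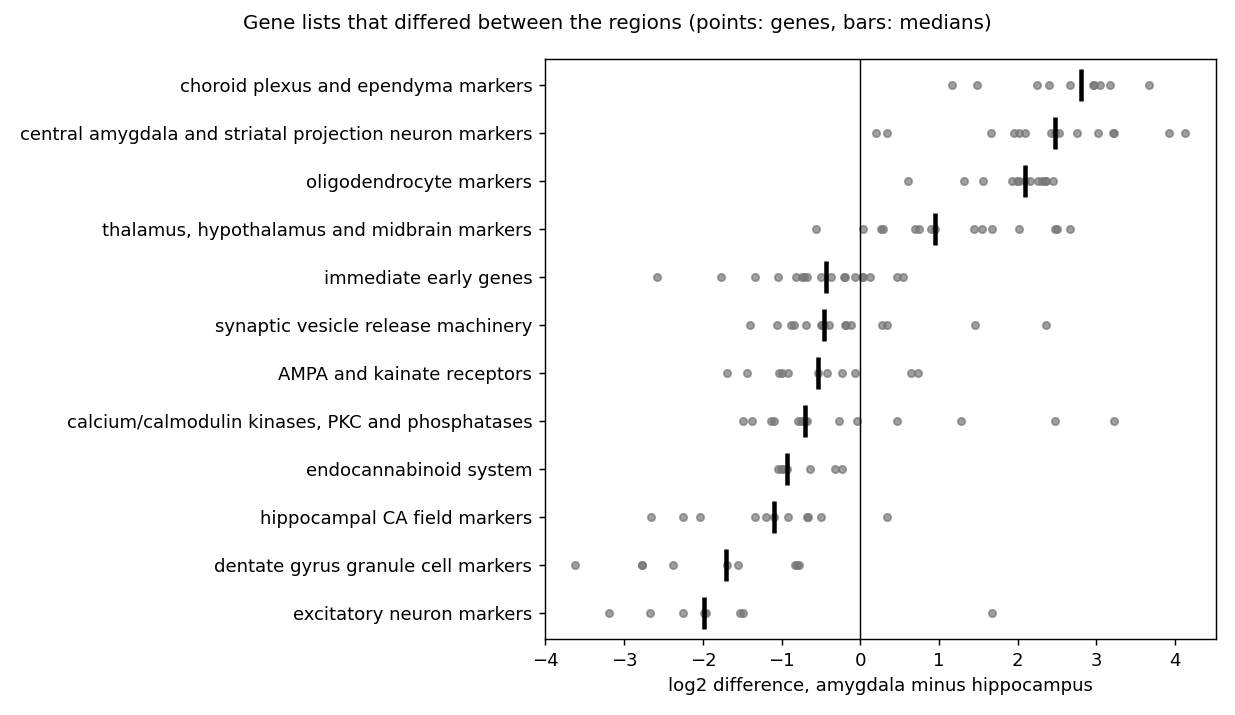
Log2 difference between amygdala and hippocampus for the 12 gene lists past the threshold. Each grey point is 1 measured gene and each black bar the list's median, which reached 2.81 for choroid plexus and ependyma markers and -1.98 for excitatory neuron markers.

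Among the functional lists, the endocannabinoid genes were lower in the amygdala without exception: 7 of 7, median log2 difference -0.929, adjusted p = 0.000248 and 0.0112 with an estimated correlation. Faah, which degrades anandamide, was 2.07-fold lower, and Cnr1, the main cannabinoid receptor of brain, 1.90-fold. Of 11 AMPA and kainate receptor genes 8 were lower and 2 higher (adjusted p = 0.00925), with Cnih2 3.23-fold, Gria1 2.70-fold and Gria2 1.99-fold lower. Immediate early genes were lower in 9 of 18 cases and higher in 2 (adjusted p = 0.00908), led by Nr4a2 (6.01-fold) and Nr4a3 (3.42-fold). The list of calmodulin kinases, protein kinase C and phosphatases had 10 lower and 4 higher members (adjusted p = 0.00946), with Camk2a 2.80-fold lower and Prkcd 5.55-fold higher. In the vesicle release list 12 of 17 were lower and 4 higher (adjusted p = 0.0178); Sv2b was 2.64-fold lower and Syt2 5.16-fold higher. For these last 4 lists the adjusted p with an estimated correlation was 0.15, 0.581, 0.479 and 0.479.

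Single members of lists that did not pass as a whole also differed. The GABA synthesis and transport genes Gad2 and Slc32a1 were 2.66- and 3.92-fold higher in the amygdala, and the interneuron marker Pvalb 3.52-fold, while Vip was 3.39-fold lower. The GABA-A receptor subunit Gabra5 was 5.23-fold lower and Gabrg1 2.42-fold higher. Bdnf, a neurotrophin of activity-dependent plasticity, was 4.97-fold lower. The mineralocorticoid receptor Nr3c2 was 4.78-fold lower, and Crh, the corticotropin-releasing hormone gene, 2.15-fold higher. Among serotonin receptors, Htr1a was 4.16-fold lower and Htr2c 2.85-fold higher. The 25 lists that did not pass as a whole had adjusted p from 0.0733, for microglia markers, to 0.978. Each gene named here passed the limma threshold with 12 arrays per region; the largest adjusted p in this group was 1.19e-09, for Crh.

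In the hippocampus, high and low freezing animals differed at few probe sets, 14 of 27022 in limma, 12 higher and 2 lower in the high freezing group. Myo7a, an unconventional myosin known from hair cells and retina, stood at 73.9 ± 20.55 intensity units in the high and 28.9 ± 6.46 in the low group (SD, n = 6 each), 1.97-fold higher (adjusted p = 0.0266). Ang, which encodes the ribonuclease angiogenin, was 2.34-fold higher (50.2 ± 10.25 against 14.4 ± 13.2 units, adjusted p = 0.0346). Rgcc, a cell cycle regulator, was 1.48-fold higher and Adgrl4, an adhesion receptor of endothelium, 1.49-fold (adjusted p = 0.0285 for both). The other probe set of Rgcc went the opposite way, with a log2 difference of -0.35 that did not pass, so the direction of this gene is not settled. These 4 are the genes called at their brightest probe set; the next by p, Snrnp40, had a log2 difference of 0.75 and an adjusted p of 0.0508.

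The other hippocampal calls were at probe sets that are not their gene's brightest or carry no symbol here, and are named after their values were seen. Higher in the high freezing group were Pgap2 (1.85-fold), Bloc1s6 (2.10-fold), Ddr1 (1.65-fold), Spon1 (1.58-fold), Ptbp2 (1.45-fold), Pan3 (1.44-fold), Gja1 (1.28-fold) and 1 unnamed probe set (1.34-fold). Of these genes' other probe sets, 0 of 2 shared the sign for Bloc1s6, 1 of 3 for Spon1, 3 of 7 for Ddr1 and 1 of 2 for Pan3. Lower were Timp2 (1.35-fold) and 1 unnamed probe set (2.33-fold). With the hippocampal arrays fitted alone the balance was 12 higher and 10 lower, and 8 of the 14 calls were among them. Of all probe sets, 3194 had an unadjusted p under 0.05, where 1351 would be expected by chance.

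The hippocampal count in limma was 0 without hippocampus low 5 or high 11, 1 without low 1 or high 8, 3 without low 3 and 4 without high 12. It was 33 without hippocampus low 2, 28 without hippocampus high 7 or amygdala high 12, 26 without amygdala low 1 and 24 without amygdala low 3.

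Among the fixed lists, 4 were lower in the high freezing hippocampus with the preset correlation, by small amounts, and no member passed over all probe sets. The list of glyoxalase and glutathione genes, which remove reactive aldehydes and peroxides, had no member above 0 among 14 (median log2 difference -0.115, adjusted p = 0.000475; alternatives from 5.7e-05 to 0.13, the last with an estimated correlation); adjusted over the list alone, 2 were lower. Gstm5 had a log2 difference of -0.17 and Gclc of -0.23. Oxidative phosphorylation genes had 4 of 26 members above 0 (median -0.0913, adjusted p = 0.000424), and cytosolic ribosomal proteins 2 of 15 (median -0.0734, adjusted p = 0.00347). With quantile normalization the medians were -0.0335 and -0.0158 and the adjusted p-values 0.264 and 0.434, in arrays whose median intensity was higher in the high group. With an estimated correlation the adjusted p-values were 0.519 and 0.541, and the lowest over the alternatives 4.62e-05 and 0.000883. Microglia markers had 2 of 12 members above 0 (median -0.0935, adjusted p = 0.0453; 0.469 with an estimated correlation, 0.0631 with the mean of a gene's probe sets, 0.0511 with quantile normalization and 0.0143 without the filter), and 1 was lower adjusted over the list alone, Trem2 with a log2 difference of -0.97.

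In the amygdala the strongest difference was Ctsc, which encodes the lysosomal protease cathepsin C: 274 ± 83.1 intensity units in the high and 636 ± 166 in the low freezing group (SD, n = 6 each), 2.26-fold lower (adjusted p = 0.00239). Fah, the last enzyme of tyrosine breakdown, was 1.40-fold lower (adjusted p = 0.0211) and Thrsp, a regulator of fatty acid synthesis, 1.28-fold (adjusted p = 0.0308). Higher in the high freezing group were Prcp, a lysosomal carboxypeptidase, at 1.83-fold, Ttc34 at 1.79-fold, Cuedc1 at 1.65-fold and the ubiquitin ligase Trim23 at 1.47-fold, with adjusted p between 0.00928 and 0.0291. In all, limma called 15 of 27022 probe sets, 10 higher and 5 lower, and 2901 had an unadjusted p under 0.05. With quantile normalization the call was 11 higher and 10 lower, and with arrays centred on their median 9 higher and 11 lower.

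The other calls of the amygdala, named after their values were seen, were at dimmer probe sets of their gene or at probe sets with no symbol here. Dclk1 (1.62-fold), Son (1.56-fold), Gmfb (1.48-fold), Mtmr6 (1.38-fold), Sirpa (1.31-fold) and 1 unnamed probe set (1.61-fold) were higher in the high freezing group. Calr, which encodes the chaperone calreticulin, was 1.38-fold lower and 1 unnamed probe set 1.46-fold lower. Among the genes called in the amygdala, 4 of 8 other probe sets shared the sign for Dclk1, 1 of 2 for Cuedc1 and 1 of 2 for Prcp.

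The main model estimates 1 spread per probe set over both regions, so the amygdalar p-values above rest partly on the hippocampal arrays. Fitted on the amygdala arrays alone, no probe set passed in limma. The 7 genes called at their brightest probe set then had adjusted p from 0.109 to 0.136, the highest over their alternatives, where the lowest was 0.000764 for Ctsc. Leaving out 1 array at a time gave 2 calls without amygdala low 1, 4 without low 3, 7 without high 8, 8 without low 5 or high 11, 35 without high 12, 50 without high 7 and 56 without low 6.

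**Figure D2:**
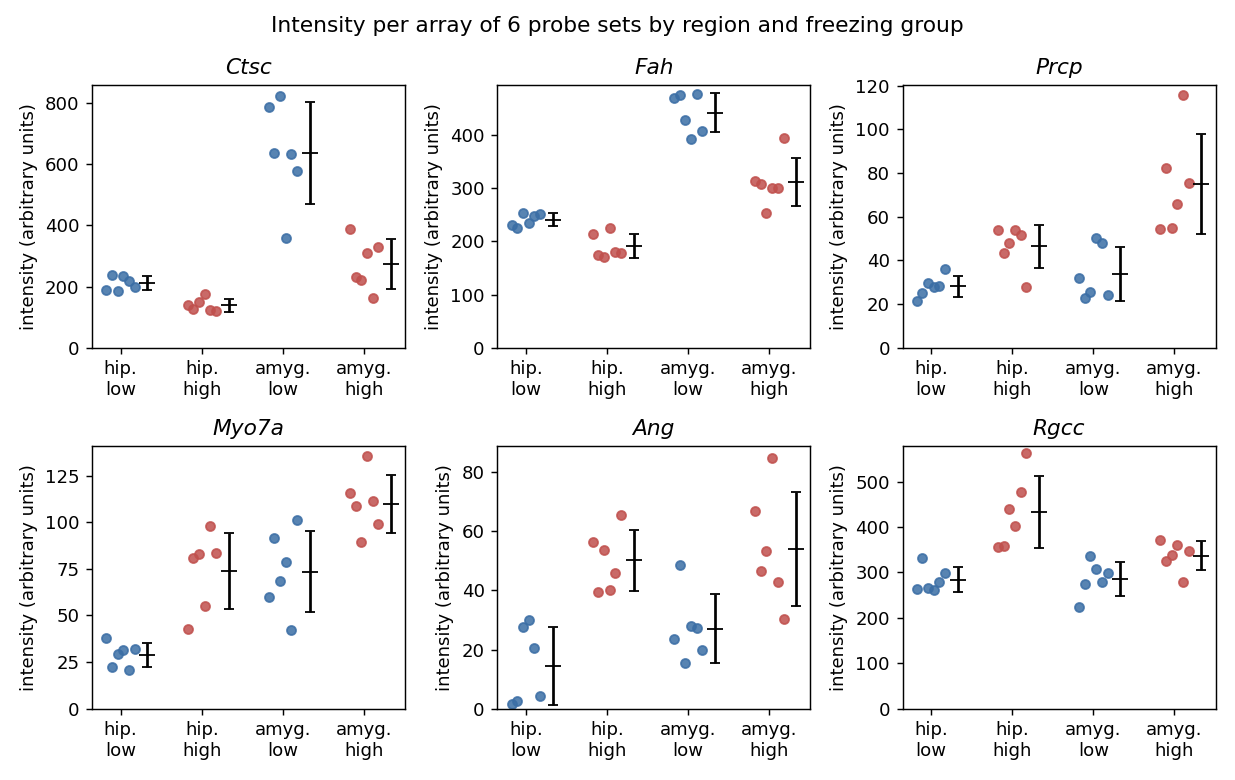
Intensity (arbitrary units, linear axis from 0) per array for 6 probe sets called in 1 of the regions, in the hippocampus and the amygdala of low (blue) and high (red) freezing animals. Points are arrays, 6 per group, and black bars the mean ± SD. Ctsc had a mean of 274 in the high and 636 in the low freezing amygdala.

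Of the fixed lists, 5 were lower and 2 higher in the high freezing amygdala with the preset correlation, and with an estimated correlation no list passed. With quantile normalization the median of the ribosomal list went from -0.0649 to -0.0214 and that of astrocyte markers from -0.0882 to -0.0545. Heat shock and protein folding genes had 2 of 14 members above 0 (median log2 difference -0.169, adjusted p = 7.45e-05; alternatives from 1.28e-05 to 0.446, the last with an estimated correlation). Adjusted over the list alone, 6 were lower and 1 higher, and none passed over all probe sets; the inducible chaperones Hspa1b and Hspa1a had log2 differences of -1.32 and -0.69. Microglia markers had 3 of 12 members above 0 (median -0.130, adjusted p = 0.00445; 0.00126 without the filter and 0.32 with an estimated correlation), with the complement genes C1qc at -0.54 and C1qb at -0.38. Astrocyte markers had 3 of 12 above 0 (adjusted p = 0.0296; 0.446 with an estimated correlation, 0.116 with quantile normalization, 0.0917 with the mean of a gene's probe sets and 0.0127 without the filter), with Gfap at -0.90. Cytosolic ribosomal proteins had 1 of 15 above 0 (adjusted p = 0.00946; 0.603 with an estimated correlation, 0.314 with quantile normalization and 0.00421 without the filter).

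None of the 15 measured markers of the central amygdala and striatum was above 0 in the high freezing amygdala (median -0.209, adjusted p = 0.00229; 0.000606 without the filter and 0.479 with an estimated correlation), with Isl1 at -0.38 and Penk at -0.26. Excitatory neuron markers had 7 of 8 members above 0 (median 0.298, adjusted p = 0.00564; 0.00517 without the filter and 0.446 with an estimated correlation), with Neurod6 at 0.60. Neuropeptides and their receptors had 16 of 23 above 0 (median 0.189, adjusted p = 0.0178; 0.0168 without the filter and 0.519 with an estimated correlation), with Cartpt at 0.67 and Tac2 at 0.34. No member of these 3 lists passed over all probe sets.

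The freezing difference was then compared between the regions. In limma's interaction test no probe set passed; 1637 had an unadjusted p under 0.05, against 1351 expected, and the smallest adjusted p was 0.706. The 5 genes with the smallest p were Col11a1, Fat4, Hspa1a, Nsfl1c and Cd82, with log2 differences of 0.79, 0.68, -0.99, 0.40 and -0.50. Of the lists, the markers of the central amygdala and striatum passed: their freezing difference was lower in the amygdala than in the hippocampus in 15 of 15 genes, 14 with quantile normalization, by a median of 0.396 on the log2 scale (adjusted p = 0.000257; 0.000269 without the filter and 0.446 with an estimated correlation). Across probe sets, which are not independent replicates, the freezing differences of both regions correlated with Pearson's r = 0.302 and Spearman's rho = 0.244, and 58.76% shared their sign. No probe set was called in both regions, where independent lists would share 0.00444 among the higher and 0.00037 among the lower.

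Averaging the freezing difference over both regions, a comparison added after the values had been seen, gave limma 284 probe sets past the threshold, 146 higher and 138 lower in high freezing animals. The genes named follow a rule like that of the other comparisons, set after the values were seen. Tmem87a was 4.10-fold higher, Rpgrip1 2.55-fold, Ang 1.95-fold and Myo7a 1.68-fold. The largest folds were the least precise: on the log2 scale the SE was 0.452 for Tmem87a and 0.301 for Rpgrip1. It was 0.162 for Ang and 0.113 for Myo7a. Hddc3 was 1.92-fold lower at 1 probe set, with its other probe set of opposite sign, Gfap, the intermediate filament of astrocytes, 1.83-fold, and Ctsc 1.82-fold. The cystine transporter gene Slc7a11 was 1.57-fold higher. All 284 had the same sign in both regions, which averaging favours, and the median size was 0.354 on the log2 scale. With arrays centred on their median 118 were higher and 208 lower. The count was 160 without hippocampus low 5 and 186 without hippocampus high 11.

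These probe sets were unevenly spread over the chromosomes. On chromosome 14, 29 of 796 named probe sets passed (3.64%), on chromosome 7, 32 of 1484 (2.16%) and on chromosome 2, 38 of 1861 (2.04%), against 1 of 978 on chromosome 17 and 5 of 1405 on chromosome 1. In chromosomal order and in bins of 40 tested genes, the densest bin lay on chromosome 2 and held 8 such genes, among them Zscan29, Golm2, B2m and Bloc1s6; its neighbour held 7, among them Ivd and Tmem87a. A bin on chromosome 7 held 7, among them Ctsc, Prcp, Thrsp and Myo7a, and a bin on chromosome 14 also held 7, among them Ang, Rpgrip1 and Rab2b.

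**Figure D3:**
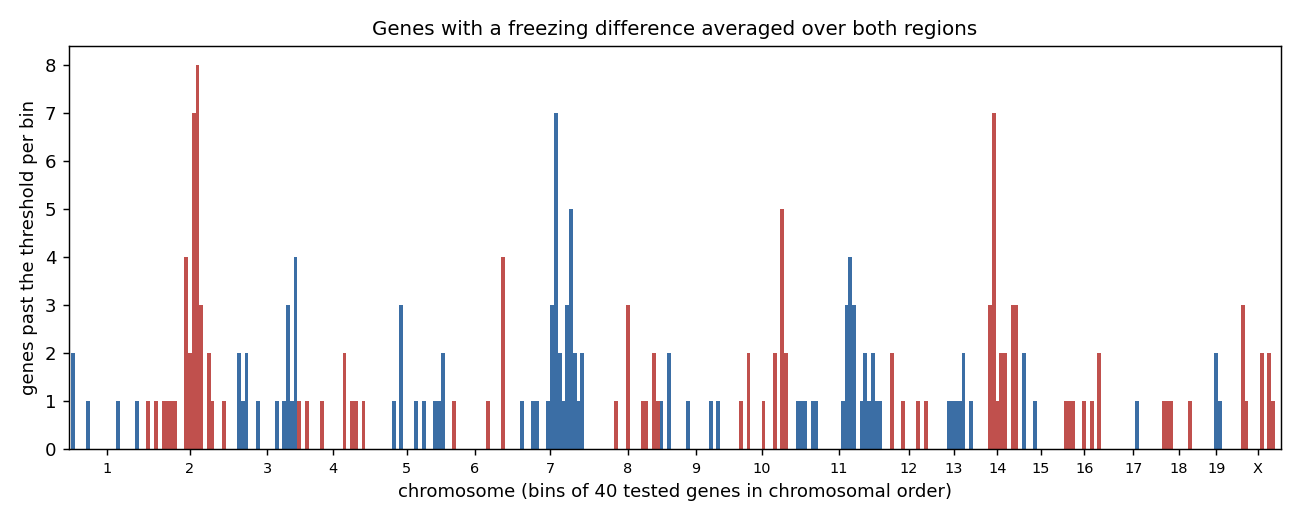
Number of genes (vertical axis) whose averaged freezing difference passed the threshold, in bins of 40 tested genes in chromosomal order, with the chromosomes named along the horizontal axis in alternating colours; the last bin of a chromosome holds fewer genes. The tallest bins, with 8 and 7 genes, lie on chromosomes 2, 7 and 14.

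Of 6 genes with known variants in the parental strains, 3 are analysed here. Gabra2, a GABA-A receptor subunit, had a log2 difference of 0.51 ± 0.18 (SE) between high and low freezing in the hippocampus (adjusted p = 0.229 in limma) and of 0.27 in the amygdala (adjusted p = 0.618). Glo1, a glyoxalase, had values of -0.33 and -0.03 (adjusted p = 0.497 and 0.976), and Nnt, the mitochondrial transhydrogenase, -0.096 and 0.059 (adjusted p = 0.876 and 0.945). Between the regions Gabra2 was 1.68-fold lower in the amygdala, and Glo1 and Nnt had log2 differences of -0.0036 and 0.0015.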

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

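The tests of the marker pattern below were chosen after the list result was seen. In groups of 6 arrays, 1 array stood apart from the rest in 4 of 82 groups tested, where chance alone gives about 1 in 20. Gmfb had an intensity of 279.2 in amygdala low 5 against 195.2 ± 13.7 in the other 5 arrays. Calr had 671.9 in amygdala high 11 against 993.7 ± 43.8, 1 unnamed probe set called in the amygdala had 138.6 in amygdala low 1 against 105.1 ± 7.33, and Gabra2 had 755.4 in hippocampus high 12 against 1087 ± 63.5.

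The freezing difference of the central amygdala and striatal markers differed between the regions, with a median of -0.396 on the log2 scale for amygdala minus hippocampus, by camera with the preset correlation (adjusted p = 0.000257). The call was lost with an estimated correlation (adjusted p = 0.446). Of the 100 genes outside the lists that follow this list closest within groups, 86 were also lower in the high freezing amygdala. The pattern thus reached beyond the list's genes. These genes were chosen for moving with the markers and are not independent of each other. Their count cannot tell a change within the neurons from a smaller share of them. A smaller share of the central nucleus or striatum in the dissected tissue may account for the pattern and stays open. The 15 markers moved together within groups with a mean correlation of 0.413. Such a share would give this, but it does not settle the cause of the difference between the groups. A different size of these nuclei between the lines stays open and untested. Taken as 1 mean per array, the list differed by -0.225 between 6 and 6 amygdala arrays, with an exact permutation p of 0.162 (0.324 adjusted over 20 such tests). Amygdala high 12 carried much of this, at 8.772 against 9.019 to 9.527 in the other high freezing arrays.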

How the results depend on the processing

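The averaged comparison, the marker covariate and quantile normalization of the correlation between regions were chosen after the data were seen. The region comparison stayed within 1.5 times its 13832 calls except where fewer features were tested: 7140 with 1 probe set per gene and 7131 with the mean of a gene's probe sets. Leaving out 1 array gave between 13523 and 13722, with fewer arrays than the full set. The interaction gave 0 in every setting and without each array. For hippocampal freezing the 14 calls became 6 without the filter on dim probe sets, 9 with the dimmest 60% left out, 5 without the variance trend, 31 with array weights, 22 with the region alone, 4 with 1 probe set per gene, 1 with the mean of a gene's probe sets and 0 with the marker covariate, with a median of 91.7% of the difference left; leaving out 1 array gave 0 to 33. For amygdalar freezing the 15 became 2 without the trend, 0 with the region alone, 7 with 1 probe set per gene, 6 with the mean of a gene's probe sets and 7 with the covariate, with a median of 98.2% of the difference left; leaving out 1 array gave 2 to 56. The averaged 284 became 171 without the trend, 137 with 1 probe set per gene, 144 with the mean of a gene's probe sets and 58 with the covariate; leaving out 1 array gave 160 to 381. Apart from the smaller numbers of features and arrays, the cause was not tested. A region fitted alone also used its own spread per probe set, where the main model shares 1 between the regions. How much this changed the counts was not tested.

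With an estimated correlation between genes, lists past the threshold went from 4 to 0 in the hippocampus, 7 to 0 in the amygdala, 12 to 3 between regions and 1 to 0 for the interaction. With quantile normalization the hippocampus kept 1 and the interaction had 2. The correlation of the freezing difference between regions was 0.189 without the filter and 0.689 over the 29 probe sets called in either region, which were selected for their size; it was 0.296 with quantile normalization.

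The settings run for single genes gave 86 values for hippocampal freezing, of which 77 kept their side of the threshold, and 108 for the amygdala, of which 96 did; no direction changed there. Between regions 1404 of 1419 kept it. The sign turned for Glo1, which was 0.0267 with quantile normalization and 0.0332 with array weights, and for Nnt, which was -0.0405 with centred arrays and -0.00632 with array weights; none of these passed.

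Both regions carry the same replicate numbers, 12 in each. Arrays of 1 number did not deviate together: 0 of 12 pairs correlated over 0.1, r lay between -0.0791 and 0.0865, and 2 of 12 arrays correlated best with their own number. With the replicate block the counts were 20, 16, 13763, 0 and 256, and the interaction had 2 lists. Dim probe sets limit the folds, since the offset of 16 is close to the lowest mean kept, 23.35 intensity units.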

Other observations

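The tests of per-array means, of the averaged comparison with its neighbours and covariate, the splits of the correlation between regions and the size of the neighbour window were chosen after the results were seen; those of other probe sets, neighbouring genes and marker lists in the 2 freezing comparisons, and the splits of the 4 planned comparisons, were fixed before.

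Taken as 1 mean per array, microglia markers were lower in the high freezing hippocampus by 0.163 on the log2 scale, 7.72 ± 0.0508 against 7.88 ± 0.0682 (SD, n = 6 each; exact permutation p = 0.00433, 0.0433 adjusted over 20 tests), and 6 of 6 high freezing arrays lay below the mean of the low ones. Trem2 carried much of this: without it the difference was -0.09 (exact p = 0.0281, not adjusted), again in 6 of 6 arrays. In the amygdala the difference was -0.159 with an exact p of 0.0346 (adjusted 0.137), with 6 of 6 arrays below the mean of the low ones, and -0.153 without Trem2. That mean was raised by amygdala low 1, 3 and 5, at 8.375, 8.312 and 8.246. Amygdala low 4 and low 6, at 8.036 and 8.006, lay within the high freezing range of 7.987 to 8.072. Excitatory neuron markers differed by 0.0823 in the hippocampus (exact p = 0.00433, adjusted 0.0433) and by 0.239 in the amygdala (exact p = 0.126, adjusted 0.28). Amygdala low 1 carried much of the latter, at 7.082 against 7.414 to 7.988 in the other low freezing arrays. The hippocampal difference did not pass the list test fixed beforehand: 5 of 8 members were above 0, with a camera adjusted p of 0.696 and 0.905 with an estimated correlation. The 20 tests of per-array means cover only part of the 37 lists, chosen after the list results were seen. Adjustment over these 20 is therefore too lenient. In the averaged comparison, 5 of 37 lists passed camera with the preset correlation, all lower in high freezing animals: cytosolic ribosomal proteins (adjusted p = 0.001), heat shock and protein folding, microglia markers, oxidative phosphorylation and the glyoxalase and glutathione list (adjusted p = 0.00122 for each of these). With an estimated correlation none passed, and the smallest adjusted p was 0.229. The Y-linked gene Eif2s3y lay between 249.6 and 394.1 intensity units on the 24 arrays.

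Other splits of the same arrays were used to ask whether chance can be excluded. For hippocampal freezing, 2 of 100 splits, the real one included, gave 14 or more probe sets. The highest other gave 25, above the real count, so such counts are uncommon in other splits but chance is not excluded. For amygdalar freezing, 5 of 100 splits gave 15 or more, so chance is not excluded. The 4 others gave 114 to 202 calls, which points to a structure among the amygdala arrays other than the freezing groups. Its source was not tested. Mean oligodendrocyte markers were 11.21, 11.03 and 11.11 in amygdala low 1, 3 and 5, against 10.89, 10.88 and 10.73 in low 2, 4 and 6. Leaving out low 1, 3 or 5 gave 2, 4 or 8 amygdalar calls. The count also fell without amygdala high 8 or high 11, to 7 and 8, and their oligodendrocyte means were 10.81 and 11.06. These counts therefore do not follow the oligodendrocyte means alone. For the regions, 1 of 100 splits reached 13832, and the highest other gave 1. For the interaction all 100 splits reached the count of 0, and the highest other gave 15. For the averaged comparison 1 of 100 reached 284, and the highest other gave 5. The correlation of 0.302 between regions lay above the 99 other splits, which ran from -0.128 to 0.168, and its covariance of 0.00869 compares with a mean of -4.75e-05 in them. The splits of the 2 regions were drawn separately for this and for the averaged comparison. They therefore leave out anything that arrays of the same number share between regions, though such arrays did not deviate together. Numbers 1 to 6 are low and 7 to 12 high freezing in both regions. Any difference in handling that followed these numbers would thus follow the freezing groups in both regions. Median intensity was higher in the high group of both regions (exact permutation p = 0.026 and 0.0281, adjusted p = 0.0843 for each). The splits cannot tell a shift in handling from a difference between the animals.

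The freezing differences lay close together on the chromosomes. Among the 25 named genes called in either region, 13 pairs lay within 50 tested genes of each other, where 2.32 would be expected, with a permutation p of 2e-04 over 10000 draws; windows of 10, 20 and 100 genes gave 0.015, 0.0052 and 1e-04, the last the smallest the draws can give. In the averaged comparison 195 pairs lay within 20 genes, and 1 of 100 splits, the real one, held as many, the highest other holding 148. This argues against neighbours that share changes however the arrays are grouped. Segments of chromosomes that differ between the selected lines, by selection or by drift, are a candidate explanation that stays open; which of these it is cannot be read from 1 pair of lines.

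A variant between the strains under single probes could give the same map without a change in expression. Of the other probe sets of the genes called in either region, 42 of 59 (71.2%, exact binomial interval 57.9 to 82.2%) shared the sign. They belong to 21 genes and are not independent, so this interval is too narrow. In the averaged comparison 66.2% shared the sign, close to the median of 64.5% in other splits. Single probe sets affected by variants thus cannot be told apart from expression for these genes as a set. In the averaged comparison, Rgcc (log2 0.40 and -0.29), Fgfr1op2 (0.49 and -0.50), Zeb2, Ngdn, Dusp3 and Hspa5 had called probe sets of opposite sign. A change of the whole gene alone cannot give this. Most genes with several called probe sets, such as Mtmr6, Gfap and Calr, had them on 1 side. If 1 line carried the allele that binds less well throughout a segment, neighbours would share their sign; 51.3% of the 195 pairs did, where 49.8% would be expected, which argues against this as the cause of the whole pattern.

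Tissue dissection stays open as a cause of the freezing differences, since 5 of 30 tests of marker lists passed in the freezing comparisons with the preset correlation, though none did with an estimated correlation, where the adjusted p ran from 0.32 to 0.479. With the marker mean of the central amygdala and striatum as a covariate, a median of 92.4% of the averaged log2 difference was left. That mean differed by -0.225 in the amygdala and by 0.104 in the hippocampus, which leaves little to remove from an average over both, so dissection cannot be told apart from other causes for these genes. For the 15 probe sets called in the amygdala, a median of 98.2% of the difference was left and 91.5% at the lower quartile. These were selected for differences large against the spread within groups. The marker mean had SDs of 0.288 (high) and 0.216 (low) within the amygdala groups, about as large as its difference between them. Little removal was thus likely for any called probe set, so this test does not decide whether the share of this tissue caused the calls. The averaged calls went from 284 to 58, 55 of them among the 284, and the amygdalar from 15 to 7, 4 of them among the 15, as standard errors grew to medians of 116% and 111% of their former size.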
